A study of Mus musculus with 14 samples.

How the data were processed

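Mouse cells were profiled by CITE-seq, in which mRNA and DNA-barcoded antibodies are counted in the same single cells, in 7 droplet libraries. The progenitor set held 3 channels, one each of double-negative (DN) thymocytes, of cells with introduced human mutant IL7R (IL7Rmut) and of cells with introduced mutant IL7R and human TLX3 (IL7Rmut+TLX3). Each of these channels was loaded with cells from 2 samples that carried different hashtag antibodies, per the labels' protocols. The passaged set held 4 libraries, 2 of leukaemia after 4 passages and 2 of DN thymocyte controls. CD4 and CD8a antibodies were used throughout, and CD11b and B220 antibodies in the passaged set, per the labels' protocols. The deposited matrices hold raw UMI counts for each gene or antibody and each filtered cell barcode, and Cell Ranger 3.1.0 with mm10 was used to make them, per the submitters' processing notes. The feature list of those matrices adds human TLX3 and the mutant human IL7R to the mouse genes, 31056 features in all, so reads of the introduced genes are counted apart from mouse Tlx3 and Il7r. Gene symbols were taken from the pairing of IDs and symbols inside the files, and the position of Ikzf2 from a mouse gene table of assembly GRCm38.p6, the assembly that mm10 holds.

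Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept, which left 9907 of 11067 in the progenitor DN channel, 6968 of 10573 in the IL7Rmut channel and 13085 of 16169 in the IL7Rmut+TLX3 channel. In the passaged set 6650 of 8128 and 9237 of 10392 DN barcodes and 7017 of 8454 and 7245 of 8490 leukaemia barcodes were kept. Hashtags were called per channel above an Otsu threshold on log counts. Cells positive for both hashtags (3.18%, 3.14% and 4.82% of the DN, IL7Rmut and IL7Rmut+TLX3 channels) were left out as doublets, and cells positive for neither (18.5%, 25.1% and 32.3%) were left out as unassigned. Hashtag counts were low (median own count 4 to 7). The calling rule raises the own hashtag's share in assigned cells (98.1% to 99.4%). A score against simulated doublets marked 1.62%, 1.49% and 0.782% of the cells of the progenitor DN, IL7Rmut and first passaged DN libraries, and these cells were left out. In the IL7Rmut+TLX3 library (0.0382%), the second passaged DN library (0.065%) and both leukaemia libraries (0.271% and 0.455%) that caller has not worked, so doublets within those libraries remain except where both hashtags showed them.

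Cells were clustered within each library by Leiden clustering on shared neighbours (2000 variable genes, 30 principal components, 20 neighbours, resolution 1), giving 19 to 30 clusters per library, so no cluster is shared between libraries. A cluster was called "X-like" from marker genes chosen before the data were examined. The rule that turned markers into names was set after the data were seen. It asked for a score of at least 0.25 and at least 1.2 times that of the next class over markers seen in at least 20% of cells, with at least 3 such markers, or for 4 markers of 1 class among the leading 10 genes. The T-lineage class was every cluster not named for another class, so it includes unnamed clusters. Clusters in which at least 25% of cells had a UMI of the introduced IL7R were called carriers of it, a threshold also set after the data were seen. The T-lineage class held 0 and 335 cells of the passaged leukaemias, so in place of the planned class the leukaemia clusters carrying the introduced IL7R were compared with the T-lineage class of the DN controls. Antibody positivity was called above an Otsu threshold over all cells of a set.

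UMI counts were summed per sample over the cells of the class compared and tested with edgeR (quasi-likelihood test with robust dispersion, TMM normalisation, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). The 6 progenitor samples entered a single fit with a mean per group, the 4 passaged libraries another, and all 10 samples a further fit that tested the difference between the passaged and the progenitor effects. B cell-like clusters of the leukaemias and of the passaged DN controls were compared as an addition after the data were seen. Gene lists, 35 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members, and again with an estimated correlation and with fry. The genes named were chosen by a rule fixed before the data were examined. It takes Ikzf1 to Ikzf5, Tlx3 and Il7r, the 8 largest rises and 8 largest falls among genes past the threshold with at least 50 CPM in the higher group and no overlap between the samples of the groups, and up to 2 rising and 2 falling members of each list described. Ribosomal, mitochondrial, haemoglobin, receptor-segment, predicted and sex-linked genes were left out of the largest changes. Normalised values are TMM-adjusted CPM (counts scaled to a common library total), and values called raw CPM are UMIs scaled in the same way by the UMIs of the same cells alone. Where all samples of a group held 0 counts, a fold was computed against 3 counts over the group, and with 1 to 3 counts a ratio is given with its counting interval. Shares of cells carry exact binomial 95% intervals in the tables behind them, and these intervals and floors cover counting error only. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs.

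Each progenitor group is 1 channel, so channel and group cannot be told apart there. The hashtagged samples and the leukaemia libraries are separate samples by the labels, but the DN controls are pools. The p-values of single genes thus measure the spread between these samples, which may be technical. Samples of the same group differed by more than sampling noise, with a chi-square per degree of freedom from 2.64 in the progenitor DN controls to 78.2 in the leukaemias. The steps were tested on simulated data drawn from the real means and library sizes. Their shares need not carry over, since the real fits called far more genes than the 200 changed. At a 4-fold change 83.5% of them were recovered for IL7Rmut+TLX3 against DN, 93% for IL7Rmut against DN, 87.5% for IL7Rmut+TLX3 against IL7Rmut, 92% for the passaged leukaemia and 76.5% for the difference of effects. At a 2-fold change the shares were 67.5%, 66%, 56%, 67% and 39%, and at a 1.5-fold change 18%, 28.5%, 21%, 36.5% and 2.5%, in the same order. Unchanged genes made up 0% to 9.88% of the calls, and over 5% for IL7Rmut against DN (5.71% at 2-fold and 5.1% at 4-fold), IL7Rmut+TLX3 against IL7Rmut (8.7% at 1.5-fold and 5.08% at 2-fold) and the passaged leukaemia (9.88% at 1.5-fold and 6.29% at 2-fold). Alternatives covered the normalisation (DESeq2 size factors), the tool (DESeq2's Wald test), the filters on genes and on cells, the hashtag and doublet rules, the cell class, non-cycling cells, the samples in a fit, a replicate block and each sample left out in turn. With a sample left out, the lone sample of its group is assumed to vary like the other groups, which give the spread. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scikit-image 0.26.0, python-igraph 0.11.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Sequencing reads were not analysed here.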

Results

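Single-cell transcriptomes and surface proteins were collected from mouse double-negative (DN) thymocytes and from the spleens of transplant recipients. DN thymocytes lack CD4 and CD8 and include the earliest committed T-cell precursors. IL7R is the interleukin-7 receptor chain that signals through JAK kinases and STAT5, TLX3 is a homeobox transcription factor expressed in a subset of human T-cell leukaemias, and the recipients of the modified cells were Rag-deficient mice. The progenitor set comprised DN controls, IL7Rmut cells and IL7Rmut+TLX3 cells, with 2 hashtagged samples per group. The passaged set comprised leukaemia after 4 passages and its own DN controls, with 2 libraries per group. The progenitor libraries held 100269591 (DN), 80741017 (IL7Rmut) and 98255669 (IL7Rmut+TLX3) UMIs in total, with medians of 5639, 4486 and 3384 UMIs per barcode. The passaged DN libraries held 120392676 and 119764812 UMIs and the leukaemia libraries 117232419 and 117688237, with medians of 9500, 7865.5, 6871 and 7132.5 per barcode. The cells compared numbered 3910 and 3325 (progenitor DN), 1646 and 1998 (IL7Rmut), 1552 and 2001 (IL7Rmut+TLX3), 5884 and 8692 (passaged DN), and 4538 and 5227 (passaged leukaemia).

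The introduced genes were detected in the IL7Rmut, IL7Rmut+TLX3 and passaged leukaemia samples and in no DN control. Transcripts of the human IL7R were present in 40.1% and 47.5% of all cells of the IL7Rmut samples, in 38.7% and 32.1% of the IL7Rmut+TLX3 cells and in 50.3% and 51.1% of the passaged leukaemia cells. No DN control cell held one, where a count of 0 allows a share of up to 0.0851% in the smallest sample. Human TLX3 was sparse, with a UMI in 0.493% and 0.482% of IL7Rmut+TLX3 cells and in 1.07% and 0.998% of passaged leukaemia cells, and it was at 0 in the IL7Rmut and DN samples. Mouse Tlx3 gave at most 2 UMIs in the cells compared of any sample.

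Cell types differed between the groups before any gene was compared. T-lineage-class cells made up 94.3% ± 0.0192 of the progenitor DN controls, 74% ± 12.8 of the IL7Rmut samples and 43.5% ± 2.16 of the IL7Rmut+TLX3 samples (SD, n = 2 each). In IL7Rmut+TLX3 samples 1 and 2, neutrophil-like clusters held 44.5% and 25.8% of the cells, and those carrying the introduced IL7R held 39.6% and 14.7%. In the passaged leukaemias 57.7% ± 1.54 of cells (SD, n = 2) were B cell-like and carried the introduced IL7R, and 64.8% and 72.5% of all cells lay in clusters that carried it. B cell-like cells made up 1.7% ± 0.338 of the passaged DN controls. With 2 samples against 2 an exact permutation test cannot go below p = 0.333, so these shares were not tested. In IL7Rmut+TLX3 sample 1, 31.6% of the T-lineage class lay in an unnamed low-UMI cluster led by Cd33, Trf, Mmp8 and Ccl6, against 2.8% in sample 2.

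**Figure D1:**
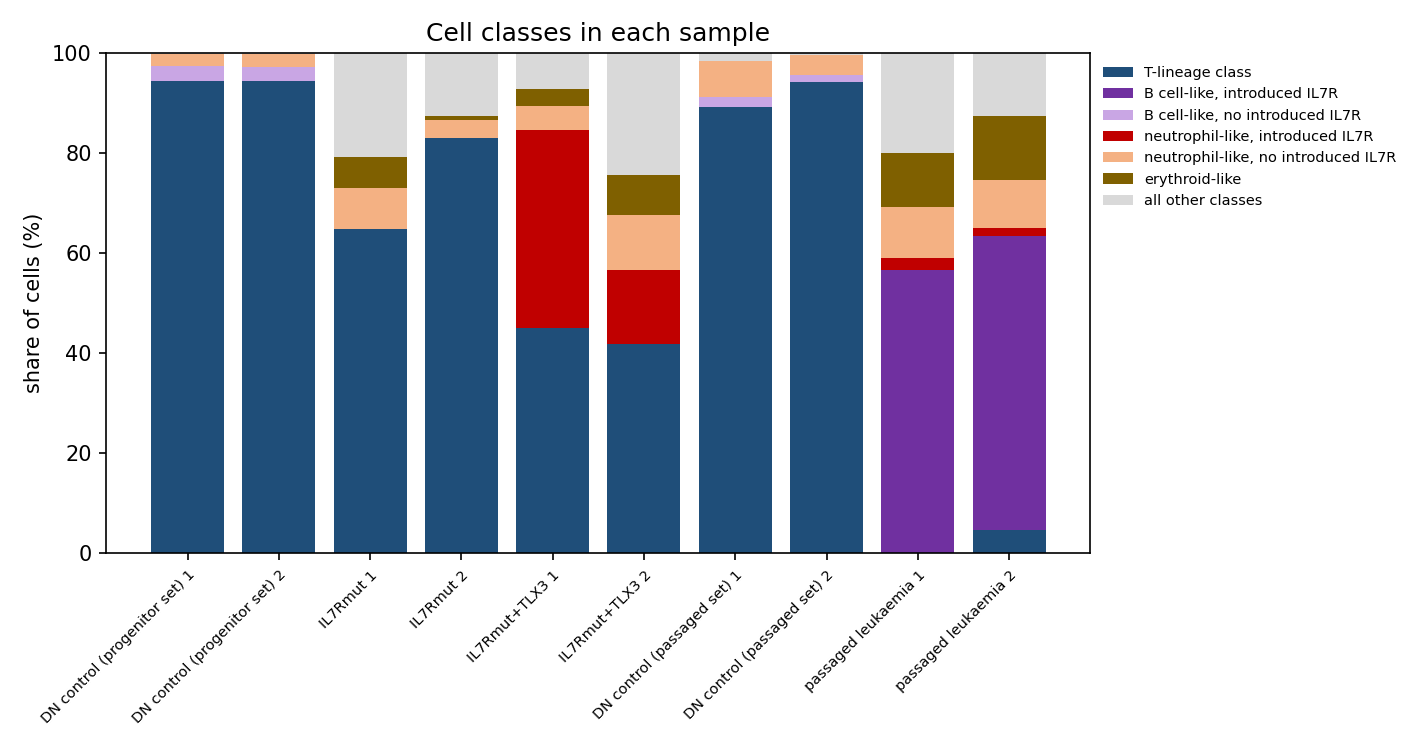
Stacked bars give the share of cells (%) in each class for each of the 10 samples, with B cell-like and neutrophil-like clusters drawn apart by whether they carry the introduced IL7R. T-lineage-class cells fill 89.2% to 94.4% of the DN controls, and B cell-like cells with the introduced IL7R fill 56.6% and 58.8% of the passaged leukaemias.

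Ikzf2 (Helios, ENSMUSG00000025997), an Ikaros-family zinc finger factor expressed in T-cell subsets, is a protein-coding gene on chromosome 1, positions 69531207 to 69687351 of the mm10 assembly. Over the cells compared, its raw level was 161 and 158 CPM in the progenitor DN samples, 335 and 326 CPM in the IL7Rmut samples, and 95.1 and 221 CPM in the IL7Rmut+TLX3 samples. The passaged DN controls held 149 and 137 CPM of Ikzf2 and the passaged leukaemias 21.6 and 24.2 CPM. Over all cells the levels were 157 and 153 CPM in progenitor DN, 203 and 275 CPM in IL7Rmut, 38.8 and 80.5 CPM in IL7Rmut+TLX3, 138 and 133 CPM in passaged DN, and 15.8 and 19 CPM in passaged leukaemia. Within IL7Rmut+TLX3 samples 1 and 2, T lineage-like clusters carried 116 and 235 CPM of Ikzf2, and neutrophil-like clusters with the introduced IL7R carried 4.88 and 12.9 CPM.

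**Figure D2:**
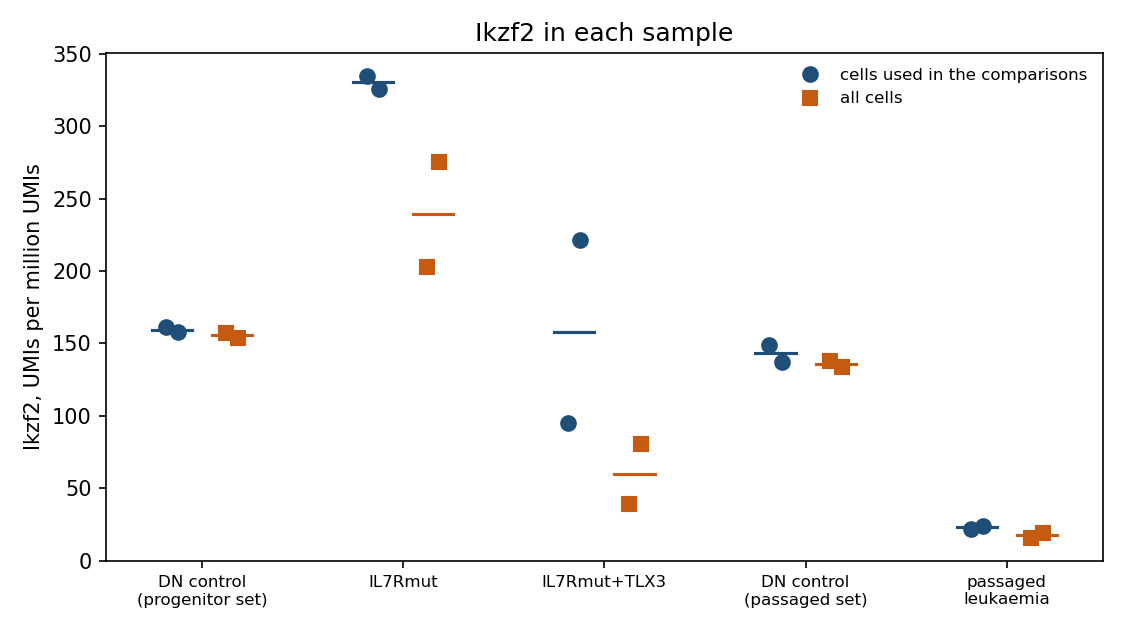
Points give the raw Ikzf2 level (CPM) of each sample, as circles over the cells compared and as squares over all cells, and short lines give the mean of the 2 samples of a group. The passaged leukaemias lie at 21.6 and 24.2 over the cells compared, and the IL7Rmut+TLX3 samples at 95.1 and 221.

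The share of cells with an Ikzf2 UMI did not rank the samples as the level did, since IL7Rmut+TLX3 sample 2 lay above both progenitor DN samples by level and below both by thinned share. Thinned to 2000 UMIs per cell, the share was 29.8% and 28.6% in progenitor DN, 35.7% and 36.7% in IL7Rmut and 17.3% and 27.5% in IL7Rmut+TLX3 (unthinned 66.9% and 66.5%, 64.3% and 67%, 22.4% and 43%). In the passaged set it was 28.2% and 25.2% in DN and 1.66% and 2.27% in leukaemia (unthinned 78.4% and 66.6%, 4.89% and 7.14%). Thinning kept 3874 and 3297 DN, 1621 and 1980 IL7Rmut, 1060 and 1818 IL7Rmut+TLX3, 5811 and 8556 passaged DN and 4456 and 5100 leukaemia cells. Neutrophil-like cells without the introduced IL7R, which should lack Ikzf2, gave thinned shares from 0.284% to 4% in the progenitor set and from 0.16% to 2.6% in the passaged set. Median depth in the cells compared ran from 3178.5 to 8243 UMIs in the progenitor set and from 8044 to 12619.5 in the passaged set. In those neutrophil-like cells it ran from 1696 to 5317 and from 4449 to 10330 UMIs.

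The first comparison set IL7Rmut+TLX3 T-lineage-class cells against DN thymocytes. The IL7Rmut+TLX3 cells include the unnamed cluster that was not called a carrier, mostly in sample 1. As in every comparison with DN, organ and transplantation cannot be told apart from the introduced genes. Ptcra, the pre-T-cell receptor chain, fell by 7.29 on the log2 scale, and Dntt, the terminal transferase that adds junctional nucleotides to receptor genes, fell by 5.20. Dntt was uneven, at 2.47 and 49 CPM in IL7Rmut+TLX3 samples 1 and 2, and fell by 4.33 without sample 1 and by 8.65 without sample 2 (Ptcra by 7.92 without sample 2). The Dntt call ended with no filter on low counts (adjusted p = 0.0631). Cytotoxic, MHC class I and STAT5 target genes rose, with Nkg7, a cytotoxic granule gene, at 1023 ± 121 CPM against 87.4 ± 1.09 CPM in DN controls (SD, n = 2 each). On their surface 63.4% ± 22 of the cells were CD8a-positive, against 0.413% ± 0.031 of DN cells, while neutrophil-like cells without the introduced IL7R in the same samples were 3.59% and 7.59% positive. At 0.5 times the antibody threshold the shares were 83.2% and 5.91%, and at 2 times 43.3% and 0.25%. In edgeR's quasi-likelihood test 4050 genes rose and 3903 fell of 12652 tested. Without DN control 1 or 2 the total was 5296 or 5116.

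Ikzf2 did not differ between IL7Rmut+TLX3 and DN T-lineage-class cells, with a log2 fold change of 0.10 ± 0.37 (SE; adjusted p = 0.825) from 161 ± 90.5 against 150 ± 1.87 normalised CPM (SD, n = 2). The samples stood on either side of the DN level, at 96.5 and 225 normalised CPM, and the fold was -0.65 without IL7Rmut+TLX3 sample 2 and 0.58 without sample 1. The adjusted p of these folds is not given, since it leaves out the gap between the samples. Over all cells, of which fewer were T-lineage, the fold was -1.19 (adjusted p = 0.0296). Of the Ikaros family only Ikzf3 (Aiolos) passed in edgeR, rising by 2.06 ± 0.18 (adjusted p = 4.3e-04), 1 of 5 members both over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.53). Ikzf1 (Ikaros) held 164 ± 10.9 and 165 ± 10.3 CPM, Ikzf4 (Eos) had a log2 fold change of 0.36 ± 0.24 (0.66 in clusters with the introduced IL7R, adjusted p = 0.0319) and Ikzf5 (Pegasus) of -0.03 ± 0.13. Mouse Il7r had a log2 fold change of 0.32 ± 0.44 (adjusted p = 0.54), and mouse Tlx3 was at 0 in all progenitor samples.

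Genes downstream of IL7R and STAT5 were among those that rose in IL7Rmut+TLX3 cells. Of 19 tested members of the IL7R-JAK-STAT5 list, 15 rose and 2 fell, the same counts when adjusted over the list alone. The kinase genes Pim2 and Pim1 rose by 4.12 ± 0.09 and 2.48 ± 0.08 on the log2 scale, while Stat5a and Stat5b themselves fell by 1.06 and 0.85. Among BCL2-family genes 12 of 15 rose and none fell, over all genes and adjusted over the list alone, led by the pro-apoptotic Bcl2l11 (Bim; 2.43 ± 0.07) and Bbc3 (Puma; 2.93 ± 0.17). Csn2, the milk casein gene known as a STAT5 target, was at least 1988-fold higher, and Nov, which encodes a secreted matricellular protein, at least 1736-fold higher than in DN controls, where both were at 0. These rises were uneven, with Csn2 at 161 and 13.8 CPM and Nov at 109 and 33.9 CPM in samples 1 and 2. The bounds were 369 and 907 without sample 1, 4323 and 2932 without sample 2, 945 and 825 without DN control 1, and 1043 and 911 without DN control 2. The Csn2 call ended without DN control 1 or 2 (adjusted p = 0.0874 and 0.0875), with no filter on low counts (0.285), with at least 1000 genes per cell (0.0597), with hashtags called by margin (0.306), in non-cycling cells (0.0865) and in clusters with the T lineage score highest (0.0582). The Nov call ended without sample 1 or 2 (adjusted p = 0.13 and 0.0959), with no filter on low counts (0.0672) and with hashtags called by margin (0.0648). Camera called both lists (adjusted p = 5.3e-04 and 7.4e-04), and neither with an estimated correlation (adjusted p = 0.405 for both).

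Effector and interferon-inducible genes formed a second rising group. All 15 MHC class I genes rose, among them H2-D1 (2.95 ± 0.08) and the peptide-loading gene Tapbp (1.81 ± 0.07). Cytotoxic and NK genes rose in 12 of 15 cases and none fell (13 adjusted over the list alone), with the transcription factor Tbx21 (T-bet) up by 4.98 ± 0.14. Regulatory T and activation genes rose in 10 of 14 cases (11 adjusted over the list alone), including the IL-2 receptor chain Il2rb (4.81 ± 0.14) and Tnfrsf18 (GITR; 3.29 ± 0.13), while Nrp1 (neuropilin-1) fell by 0.99. The Nrp1 call ended over all cells (-0.53, adjusted p = 0.136), in clusters with the introduced IL7R (-0.55, adjusted p = 0.101), in non-cycling cells (adjusted p = 0.0556) and without DN control 1 (adjusted p = 0.0517). Of 24 interferon-response genes 18 rose and 1 fell, and the same counts were reached adjusted over the list alone. Gbp2, a guanylate-binding protein gene, rose by 3.04 ± 0.10. Ifi44 was 18.1-fold lower by ratio of counts (counting interval 6.13 to 88.7) and was at 0.29 over all cells, and its call also ended with hashtags called by margin (adjusted p = 0.0755). Camera adjusted p was 3.4e-06 for MHC class I, 1.1e-04 for cytotoxic, 5.3e-04 for regulatory T and 0.0013 for interferon genes, and with an estimated correlation the adjusted p was 0.431, 0.405, 0.419 and 0.467.

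Cell-cycle, MYC target and T-lineage transcription factor genes fell in IL7Rmut+TLX3 cells. All 39 S-phase genes fell, including the ubiquitin ligase genes Dtl (-2.23 ± 0.08) and Uhrf1 (-2.28 ± 0.10). So did 20 of 23 MYC targets, such as Nolc1 (-1.09 ± 0.06) and Hspd1 (-1.04 ± 0.05), with equal counts adjusted over each of these lists alone. Of 51 G2 and M phase genes 32 fell and 3 rose on both counts, with the chromatin genes Anp32e (-1.54 ± 0.09) and Cbx5 (-0.99 ± 0.06) down and Cenpa (0.40 ± 0.09) and Tubb4b (0.28 ± 0.08) up. The calls of these rises ended without DN control 1 or 2 (adjusted p = 0.0794 and 0.0746 for Cenpa, 0.135 and 0.166 for Tubb4b), and that of Tubb4b also without IL7Rmut+TLX3 sample 1 (0.0511), with no filter on low counts (0.0701) and with all 10 samples in a single fit (0.0655). T-lineage transcription factors fell in 13 of 19 cases and rose in 3, the same adjusted over the list alone. The E protein gene Tcf3 and Runx1 fell by 2.52 and 1.93, while Runx3, a CD8-lineage factor, rose by 1.84 ± 0.10 and Zbtb7b (ThPOK) by 4.52 ± 0.26. Of 13 Notch genes 7 fell and 2 rose, also adjusted over the list alone, with Notch1 (-1.99 ± 0.10) and its target Myc (-1.12 ± 0.08) down and Notch2 (1.50 ± 0.27) and Dtx1 (1.31 ± 0.40) up, but the list was not called (camera adjusted p = 0.0713). The Dtx1 call ended over all cells (0.04, adjusted p = 0.935), in clusters with the introduced IL7R (0.72, 0.24), in non-cycling cells (0.22, 0.624), with no filter on low counts (0.123) and with only these groups in the fit (0.0582). It also ended without DN control 1 or 2 (1.44 and 1.16, adjusted p = 0.111 and 0.167), IL7Rmut sample 1 or 2 (0.0584 and 0.0595) or IL7Rmut+TLX3 sample 2 (0.58, 0.162). The other lists were called at adjusted p = 2.8e-11 (S phase), 1.3e-05 (MYC), 1.1e-04 (G2 and M) and 0.019 (transcription factors), and at none with an estimated correlation (adjusted p = 0.413, 0.413, 0.587 and 0.51). The G2 and M call was also lost in clusters carrying the introduced IL7R (adjusted p = 0.11) and in non-cycling cells (adjusted p = 0.071). Further DN genes with large falls were Dgkeos (-5.55 ± 0.79), Tmem121 (-4.28 ± 0.36), the Hedgehog transducer Smo (-4.17 ± 0.16), Ptov1 (-3.90 ± 0.32), Arpp21 (-3.90 ± 0.66) and the E protein gene Tcf4 (-3.71 ± 0.65). Of these Dgkeos stood at 0.37 and 4.79 CPM, Arpp21 at 9.99 and 42.4 CPM and Tcf4 at 0.616 and 6.58 CPM in samples 1 and 2. Without sample 1 these 3 genes fell by 4.83, 3.25 and 2.97, and without sample 2 by 8.51, 5.34 and 6.38 (Tmem121 by 5.19). The Tcf4 call ended over all cells (-1.79, adjusted p = 0.0502).

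Neutrophil transcripts moved with the IL7Rmut+TLX3 group in the same cells, and carry-over from neutrophil-like cells was not ruled out. All 11 neutrophil genes and all 12 monocyte and macrophage genes tested rose, also adjusted over each list alone. Ngp and Camp, granule proteins of immature neutrophils, stood at 365 ± 52.1 and 232 ± 24.1 CPM against 3.68 ± 0.13 and 3.36 ± 0.047 CPM, and Lyz2 and Ccr2 of monocytes rose by 4.54 ± 0.22 and 2.74 ± 0.17. These calls had a camera adjusted p of 5.3e-06 and 7.9e-05, and with an estimated correlation the adjusted p was 0.413 and 0.405. The largest rises included the stefin A protease inhibitors of the neutrophil lineage. Stfa2 was 16194-fold higher by ratio of counts (2905 to 639799) and Stfa2l1 4468-fold (1528 to 21679), while the pyrimidine salvage gene Upp1 was 4206-fold (753 to 166282) and Stfa1 1716-fold higher (586 to 8332). Stfa3 rose by 11.67 ± 1.07 and BC100530, another stefin gene, by 11.13 ± 0.95. These rises were uneven, with Stfa2 at 368 and 85.8 CPM, Stfa2l1 at 319 and 61.1 CPM and Upp1 at 97.4 and 21 CPM in samples 1 and 2. Without sample 1 Stfa3 stood at 10.77 and BC100530 at 10.12, and without sample 2 BC100530 stood at 11.72. DN control 1 held 0 counts of Stfa3, which stood at 10.65 without it, and BC100530 was at 10.33 without DN control 1 and 12.66 without DN control 2. The Stfa2 call ended in non-cycling cells (adjusted p = 0.0659). Clusters with the T lineage score highest leave out the unnamed cluster of mostly sample 1 cells led by Cd33 and Mmp8, and there BC100530 stood at 9.41. Clusters with the introduced IL7R take in neutrophil-like ones, and there BC100530 stood at 14.97 and Stfa3 at 14.47. Dendritic cell genes rose in 7 of 7 cases and erythroid genes in 9 of 11, also adjusted over each list alone (camera adjusted p = 0.0011 and 6.2e-04, and adjusted p = 0.423 and 0.413 with an estimated correlation). Over all cells other rises of this comparison were smaller, with Ikzf3 at 0.63, Pim2 at 2.83, Nkg7 at 2.83, Tbx21 at 3.60, Il2rb at 3.53, Tnfrsf18 at 2.23, Bcl2l11 at 1.51, Bbc3 at 1.97, Runx3 at 0.91, Ngp at 5.03, Camp at 4.78 and Lyz2 at 3.12, and Tcf3 stood at -1.58 and Ptov1 at -2.68. In raw counts, T lineage-like clusters of IL7Rmut+TLX3 samples 1 and 2 held 119 and 202 CPM of Camp, and neutrophil-like clusters with the introduced IL7R 12701 and 18667 CPM.

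The second comparison addressed mutant IL7R alone. IL7Rmut T-lineage-class cells carried CD8 and cytotoxic genes that DN thymocytes held at low levels. Cd8a, the CD8 co-receptor chain, stood at 710 ± 22.1 CPM against 4.53 ± 0.246 CPM (SD, n = 2 each), and 90.9% ± 1.68 of the cells were CD8a-positive by antibody against 0.413% ± 0.031 of DN cells and 11.7% and 4.55% of neutrophil-like cells in the IL7Rmut samples. CD4 antibody marked 30.9% ± 8.95 of IL7Rmut cells and 0.663% ± 0.00234 of DN cells, with 8.25% and 5.68% among those neutrophil-like cells. At 0.5 times the threshold CD4 marked 59.6% of IL7Rmut and 21.5% of DN cells, and at 2 times 16.2% and 0.289%. In edgeR 3696 genes rose and 3499 fell of 12652 tested, and without DN control 1 or 2 the total was 4042 or 4064.

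Ikzf2 was higher in IL7Rmut than in DN cells, at 346 ± 1.92 against 150 ± 1.87 normalised CPM, a log2 fold change of 1.204 ± 0.372 (SE; edgeR adjusted p = 0.041) with both samples above both controls. The call ended, with the direction unchanged, without either DN control (1.19 and 1.17, adjusted p = 0.166 and 0.175), without IL7Rmut sample 1 or 2 (1.196 and 1.2045, adjusted p = 0.126 and 0.127), with no filter on low counts (1.14, adjusted p = 0.149), over all cells (0.69, adjusted p = 0.141), in non-cycling cells (0.33, adjusted p = 0.5) and in clusters with the introduced IL7R (1.202, adjusted p = 0.0781). Ikzf3 rose by 2.68 ± 0.18 (adjusted p = 2.4e-04). Of 5 Ikaros genes 2 rose (1 adjusted over the list alone) and the list was not called (camera adjusted p = 0.47). Ikzf1 had a log2 fold change of 0.03 ± 0.07, Ikzf4 of -0.19 ± 0.24, Ikzf5 of -0.09 ± 0.13 and Il7r of 0.23 ± 0.43, none past the threshold.

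Effector, signalling and MHC genes rose in IL7Rmut cells. Of 15 cytotoxic and NK genes 13 rose, over all genes and adjusted over the list alone, with Nkg7 up by 3.78 ± 0.09. Of 14 regulatory T and activation genes 13 rose and 1 fell on both counts, with Il2rb (4.80 ± 0.14) and Tnfrsf18 (3.22 ± 0.13) up and Nrp1 (-1.97 ± 0.21) down. The largest rises were Cdkn2a, the tumour suppressor locus of p16 and p19ARF (10.33 ± 0.89), Ifitm1 (7.61 ± 0.68), Jchain (7.56 ± 1.24), Cd8a (7.29 ± 0.59), the granzyme gene Gzmb (6.41 ± 1.01), Gramd3 (6.36 ± 0.17), the chemokine gene Ccl5 (6.33 ± 0.78) and the inhibitory receptor gene Lag3 (6.07 ± 0.34). Cdkn2a was at 9.43 without DN control 2, and its 5 control counts all lay in DN control 1. Ifitm1, at 479 and 209 CPM in the IL7Rmut samples, was at 6.89 without sample 1. The Jchain call ended without DN control 1 or 2 (adjusted p = 0.0522 and 0.0537). All 15 MHC class I genes rose, H2-D1 to 2183 ± 8.77 from 254 ± 1.39 CPM and H2-Q6 by 5.08 ± 0.18. Of 19 IL7R-JAK-STAT5 genes 14 rose and 3 fell (14 and 5 adjusted over the list alone), with Pim2 (3.94 ± 0.09) and Pim1 (2.06 ± 0.08) up, Stat5b (-0.93 ± 0.08) down and Stat5a down to 32.6 ± 0.483 from 65.4 ± 1.49 CPM. BCL2-family genes rose in 10 of 15 cases on both counts, among them Bcl2 (2.75 ± 0.15) and Bcl2l11 (2.67 ± 0.07). By camera the adjusted p was 1.3e-05 (cytotoxic), 6.3e-05 (regulatory T), 1.1e-07 (MHC class I), 0.0029 (IL7R-JAK-STAT5) and 0.0029 (BCL2), and none of these was called with an estimated correlation (adjusted p = 0.349, or 0.44 for MHC class I). T-cell receptor genes rose in 13 of 20 cases (13 up and 1 down adjusted over the list alone), with the CD45 gene Ptprc up by 1.43 ± 0.08. That list was called at adjusted p = 0.0035, but not over all cells (adjusted p = 0.13) nor with an estimated correlation (adjusted p = 0.641).

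S-phase, MYC target and Notch genes fell in IL7Rmut cells. Of 39 S-phase genes 33 fell (34 adjusted over the list alone), with Dtl at -1.88 ± 0.07 and Uhrf1 at -1.53 ± 0.10. Of 23 MYC targets 20 fell and 1 rose (21 and 1 adjusted over the list alone), with Nolc1 (-1.04 ± 0.06) and Hspd1 (-0.96 ± 0.05) down and the lactate dehydrogenase gene Ldha (0.35 ± 0.05) up. Notch genes fell in 7 of 13 cases and rose in 1 on both counts, with Notch1 (-2.34 ± 0.10) and Hes1 (-6.81 ± 0.40) down and Dtx1 (1.31 ± 0.39) up. These lists were called at adjusted p = 1.1e-07, 1.3e-05 and 0.014, and with an estimated correlation the adjusted p was 0.444, 0.349 and 0.349. The Ldha call ended over all cells (0.07, adjusted p = 0.471) and without DN control 1 (0.0554). The Dtx1 call ended over all cells (0.95, adjusted p = 0.0967), in clusters with the introduced IL7R (0.0654), in non-cycling cells (0.08, 0.879) and with no filter on low counts (0.129). It also ended without DN control 1 or 2 (adjusted p = 0.126 and 0.186) and without IL7Rmut sample 1 or 2 (0.0721 and 0.162). Other thymocyte and cycle lists were not called. G2 and M genes fell in 16 of 51 cases and rose in 5 (13 and 4 adjusted over the list alone; camera adjusted p = 0.129, but 0.00176 over all cells). T-lineage transcription factors fell in 9 of 19 and rose in 4 on both counts (camera adjusted p = 0.209, but 0.0187 over all cells), and double-positive thymocyte genes fell in 3 of 13 and rose in 3 on both counts (camera adjusted p = 0.806). The genes with the largest falls were Adgrg1 (-5.48 ± 0.58), Ptcra (-5.25 ± 0.38), the aldehyde dehydrogenase gene Aldh2 (-4.99 ± 0.56), Tmem121 (-4.62 ± 0.35), Dntt (-4.26 ± 1.04), Smo (-4.02 ± 0.15), Dnph1 (-3.94 ± 0.29) and Zfp704 (-3.88 ± 0.54). Without IL7Rmut sample 1 Ptcra fell by 6.10 and Dnph1 by 4.55, and without sample 2 Zfp704 fell by 4.52. The Dntt call ended without DN control 1 or 2 (adjusted p = 0.0804 and 0.0809), without IL7Rmut sample 1 or 2 (0.09 and 0.123), with no filter on low counts (0.0939) and in non-cycling cells (0.0559). Over all cells Hes1 stood at -3.57, Adgrg1 at -3.24, Aldh2 at -1.07 and Dnph1 at -2.16. Genes of other cell types rose in the same IL7Rmut cells. Neutrophil genes rose in 7 of 11 cases on both counts, Elane to 0.772 ± 0.21 from 0.175 ± 0.0122 CPM and Ltf to 2.79 ± 1.03 from 0.819 ± 0.0483 CPM, and monocyte genes in 9 of 12 (10 adjusted over the list alone), with Ctss up by 3.55 ± 0.22 and Ccr2 by 1.91 ± 0.17. Camera adjusted p was 0.011 and 0.0029, with an estimated correlation adjusted p = 0.53 and 0.349, and the neutrophil call ended in non-cycling cells (adjusted p = 0.13), as did those of Elane (0.118), Ltf (0.218) and Ccr2 (0.37 on the log2 scale, 0.134). The Ltf call also ended over all cells (0.80 on the log2 scale, adjusted p = 0.24), with hashtags called by margin (0.0565), without the top doublet scores (0.102) and with all 10 samples in a single fit (0.0839). Dendritic cell genes rose in 7 of 7 cases and erythroid genes in 6 of 11, also adjusted over each list alone (camera adjusted p = 0.0029 and 0.0055, and adjusted p = 0.444 and 0.44 with an estimated correlation).

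**Figure D3:**
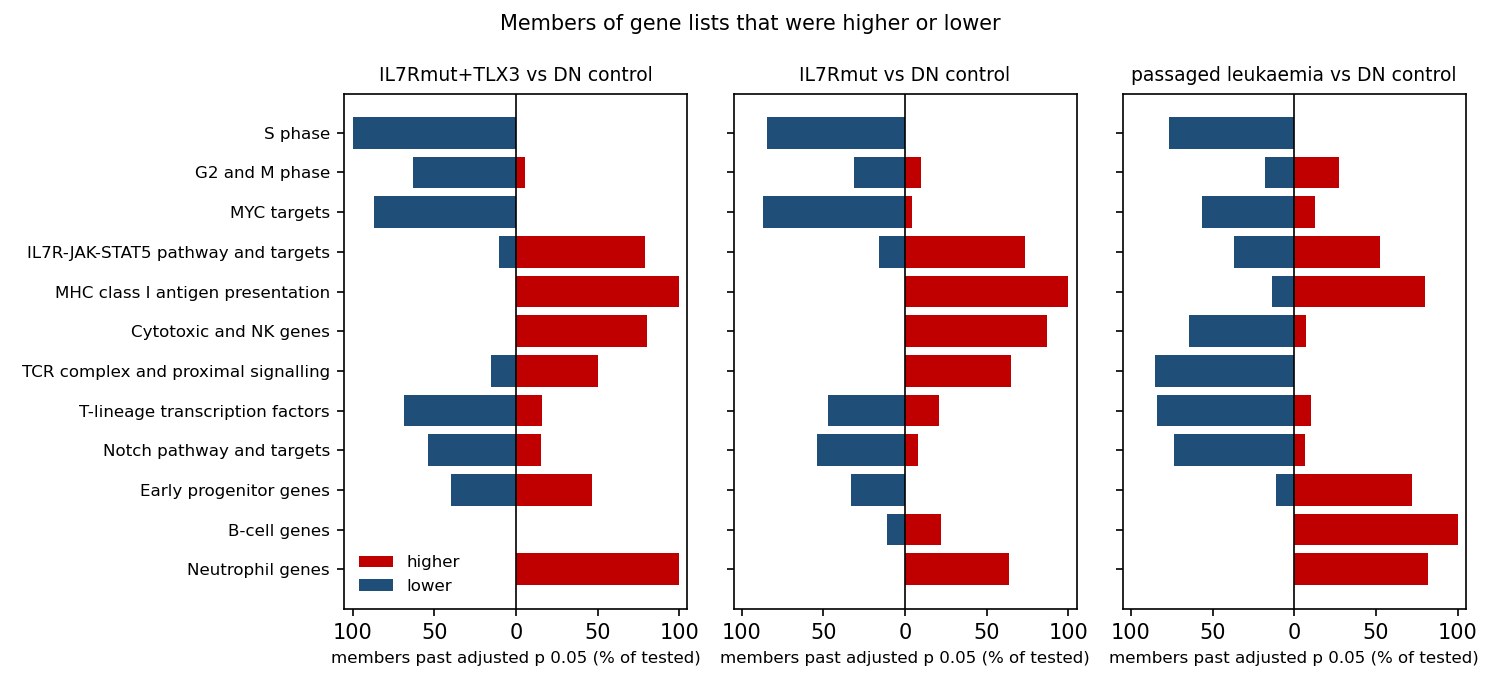
Bars give, for 12 gene lists in 3 comparisons, the share of tested members (%) past an adjusted p of 0.05, with higher members to the right in red and lower members to the left in blue. S-phase genes lie to the left in all 3 panels, and B-cell genes reach 100% on the right in the panel of the passaged leukaemia alone.

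The third comparison set IL7Rmut+TLX3 against IL7Rmut T-lineage-class cells. Neutrophil genes were the clearest difference, with all 11 higher in IL7Rmut+TLX3 cells and Ngp at 365 ± 52.1 against 5.65 ± 0.264 CPM (SD, n = 2 each). Cd2, an adhesion receptor gene, and Skap1, an adaptor gene of T-cell receptor signalling, were lower, each at a log2 fold change of -1.55, while 1 of 20 T-cell receptor genes was lower. In edgeR 952 genes rose and 826 fell of 12652 tested. That total depended on the samples in the fit. It fell sharply without any 1 of the DN controls or IL7Rmut samples. It rose without either IL7Rmut+TLX3 sample, where the other groups give the spread. Of the genes named for this comparison only Ngp, Camp and Lyz2 passed in all 4 of the fits that left out a DN control or an IL7Rmut sample, and Gramd3 and Tcf3 passed without either DN control but not without either IL7Rmut sample. The total was 10 with only these groups in the fit, 258 in non-cycling cells and 3984 in clusters with the introduced IL7R.

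Ikzf2 had a log2 fold change of -1.10 ± 0.37 between IL7Rmut+TLX3 and IL7Rmut cells, which did not pass (edgeR adjusted p = 0.109), from 161 ± 90.5 against 346 ± 1.92 normalised CPM. Both IL7Rmut+TLX3 samples, at 96.5 and 225, were below both IL7Rmut samples, at 347 and 345. The difference passed over all cells (-1.88, adjusted p = 0.0371) and in clusters with the introduced IL7R (-1.69, adjusted p = 0.0474). Without IL7Rmut+TLX3 sample 1 or 2 it was -0.61 and -1.85. None of the 5 Ikaros genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.63), with Ikzf3 at -0.62 ± 0.17 (-1.40 over all cells, adjusted p = 0.0272, and -1.24 in clusters with the introduced IL7R, adjusted p = 0.0277), Ikzf1 at -0.03 ± 0.08, Ikzf4 at 0.55 ± 0.25 (0.85 in clusters with the introduced IL7R, adjusted p = 0.0315) and Ikzf5 at 0.05 ± 0.14. Il7r had a log2 fold change of 0.09 ± 0.44.

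The largest rises here were in genes of the neutrophil lineage. Neutrophil-like cells were 35.1% of IL7Rmut+TLX3 and 5.89% of IL7Rmut samples, so their carry-over was again not ruled out. BC100530 was 5718-fold higher by ratio of counts (1582 to 47228) and Stfa2 2424-fold (829 to 11760), and Stfa1 (8.87 ± 0.57), Stfa2l1 (8.81 ± 1.24), Stfa3 (8.70 ± 0.92), the neutrophil collagenase gene Mmp8 (8.13 ± 1.38), the myeloid receptor gene Cd33 (8.07 ± 1.52) and Chil3 (7.37 ± 1.03) rose. Mmp8 and Cd33 lead the unnamed cluster of mostly sample 1 cells, which was not called a carrier of the introduced IL7R. BC100530 stood at 526 and 171 CPM and Stfa2 at 368 and 85.8 CPM in samples 1 and 2. Mmp8 and Cd33 stood at 181 and 152 CPM in sample 1 and at 26.3 and 17.2 CPM in sample 2, and in clusters with the T lineage score highest at 4.98 and 5.17 on the log2 scale, with Stfa1 at 7.81, Stfa2l1 at 6.11, Stfa3 at 6.53 and Chil3 at 5.29. Without IL7Rmut+TLX3 sample 1 the rises of Mmp8, Cd33, Chil3, Stfa2l1 and Stfa3 were 6.19, 5.80, 5.78, 7.19 and 7.80, and without sample 2 those of Mmp8, Cd33, Chil3 and Stfa2l1 were 8.94, 8.93, 8.11 and 9.55. Without IL7Rmut sample 1 Stfa1, Stfa2l1 and Stfa3 rose by 8.23, 9.72 and 10.92, and without sample 2 by 10.07, 8.22 and 7.82 (Mmp8 by 8.77). Calls that ended in non-cycling cells were those of all 8 of these genes, of Lyz2, Fcgr3 and Spi1 (adjusted p from 0.0587 to 0.182). Camp rose by 5.92 ± 0.18, and of 12 monocyte genes 7 rose (11 adjusted over the list alone), Lyz2 by 3.91 ± 0.22 and the Fc receptor gene Fcgr3 by 4.71 ± 0.60. Early progenitor genes rose in 4 of 15 cases (10 adjusted over the list alone), including the stem-cell factor receptor Kit (1.94 ± 0.25) and the myeloid factor Spi1 (PU.1; 5.02 ± 0.86), which did not pass in clusters with the T lineage score highest (adjusted p = 0.0552). Over all cells Mmp8, Cd33, Chil3 and Stfa2l1 stood at 3.13, 3.70, 4.17 and 5.72, Ngp and Camp at 4.27 and 4.28, and Fcgr3 and Spi1 at 1.88 and 1.39. The calls of Kit (0.21, adjusted p = 0.628) and Lyz2 (1.55, adjusted p = 0.0724) ended there. Without IL7Rmut+TLX3 sample 1 Spi1 rose by 3.64 and Fcgr3 by 3.98, and Spi1 rose by 5.73 without sample 2 and by 5.67 without IL7Rmut sample 1. Camera called the neutrophil (adjusted p = 5.4e-12), monocyte (1.5e-05) and progenitor (2.1e-04) lists, none with an estimated correlation (adjusted p = 0.575, 0.528 and 0.659), and the monocyte call was lost over all cells (adjusted p = 0.49).

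Falls in this comparison were smaller. Ldhb (-2.69 ± 0.61), Gramd3 (-2.51 ± 0.14), the NK receptor gene Klrd1 (-1.67 ± 0.34), Tcf3 (-1.58 ± 0.08), Drc1 (-1.50 ± 0.32) and Rgs10 (-1.37 ± 0.26) fell most beside Cd2 and Skap1, and the call of Ldhb ended in clusters with the T lineage score highest (adjusted p = 0.0558). Without IL7Rmut+TLX3 sample 1 or 2 neither Ldhb (-2.05 and -4.31, adjusted p = 0.161 and 0.0635) nor Klrd1 (-1.47 and -1.92, adjusted p = 0.233 and 0.138) passed, and without sample 2 Cd2 and Skap1 fell by 2.16 and 2.18. Over all cells the calls of Klrd1 (adjusted p = 0.0685), Rgs10 (0.0784), Ets2 (-0.45, 0.176), Mcm5 (-0.10, 0.437), Atp5g3 (0.0642) and Uqcrc2 (0.0581) ended, and that of Mcm5 ended in clusters with the introduced IL7R (-0.21, adjusted p = 0.15). In non-cycling cells the calls of Ldhb, Klrd1, Drc1, Mcm6, Mcm5, Smc4, Ndc80, Atp5g3, Uqcrc2 and Ets2 ended (adjusted p from 0.0521 to 0.158). Rises and falls that ended with no filter on low counts were Stfa2, Stfa2l1, Mmp8, Cd33, Chil3, Spi1, Ldhb, Klrd1, Cd2, Skap1, Drc1 and Rgs10 (adjusted p from 0.0518 to 0.144). Those that ended with hashtags called by margin were Stfa2, Cd33, Ldhb, Klrd1, Cd2, Skap1, Rgs10, Ndc80 and Ets2 (adjusted p from 0.0524 to 0.191), and Trbc2 did not pass with all 10 samples in a single fit (adjusted p = 0.399). T-lineage transcription factors fell in 5 of 19 cases and rose in 1 (6 and 2 adjusted over the list alone), with Ets2 down by 0.75 and Zbtb7b up by 1.35 ± 0.22, and of 20 T-cell receptor genes only Trbc2, the T-cell receptor beta constant region, fell (-0.87 ± 0.11; also 1 adjusted over the list alone). S-phase genes fell in 29 of 39 cases (34 adjusted over the list alone), Mcm6 and Mcm5 of the replicative helicase by 0.54 and 0.51. G2 and M genes fell in 12 of 51 cases (24 adjusted over the list alone), Smc4 and Ndc80 by 0.59 and 0.50 (Ndc80 not with the T lineage score highest, adjusted p = 0.0517). Oxidative phosphorylation genes fell in 21 of 84 cases (36 down and 1 up adjusted over the list alone), Atp5g3 and Uqcrc2 by 0.38 and 0.36. These calls had a camera adjusted p of 0.037 (transcription factors), 0.0053 (T-cell receptor), 5.4e-12 (S phase), 9.5e-07 (G2 and M) and 3.4e-07 (oxidative phosphorylation), and with an estimated correlation the adjusted p was 0.667, 0.715, 0.659, 0.667 and 0.667. The G2 and M and oxidative phosphorylation calls were lost over all cells (adjusted p = 0.85 and 0.2) and in clusters with the introduced IL7R (adjusted p = 0.64 and 0.15). Neutrophil transcripts differed beside each of these lists.

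The fourth comparison addressed leukaemia after 4 passages. Its cells with the introduced IL7R had a B-cell precursor profile in place of a T-cell one. Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B-cell receptor, stood at 444 ± 49.1 and 1328 ± 167 CPM against 0.14 ± 0.0107 and 3.65 ± 0.111 CPM in DN T-lineage-class cells (SD, n = 2 each), while Cd3d, a chain of the T-cell receptor complex, fell by 10.45 on the log2 scale. The B220 antibody marked 98.6% and 99% of B cell-like leukaemia cells at median counts of 702 and 653, and 98.4% and 95.6% of B cell-like DN cells at 3478.5 and 3441. Neutrophil-like cells without the introduced IL7R of the leukaemia libraries, which should lack B220, were 57.3% and 81.5% positive. Of 15294 genes tested with edgeR, 4811 rose and 4652 fell. Sex-linked transcripts moved with the leukaemia, with a UMI of Xist in 0.186% and 0.139% of all leukaemia cells against 95.6% and 96.8% of all passaged DN cells, and of the Y-linked gene Ddx3y in 37.9% and 39.3% against 0.0303% and 0%. No progenitor cell held Ddx3y.

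Ikzf2 fell in the passaged leukaemia, to 22.5 ± 2.15 from 146 ± 3.84 normalised CPM, a log2 fold change of -2.69 ± 0.10 (edgeR adjusted p = 9.9e-07) with both leukaemias below both controls. Its raw level within the leukaemia differed by class. B cell-like cells held 0.854 and 0.969 CPM in leukaemia 1 and 2, erythroid-like cells with the introduced IL7R 30.9 and 16.4 CPM, mast or basophil-like cells of leukaemia 1 298 CPM and the unnamed cells of leukaemia 2 192 CPM. Ikzf1 fell by 0.55 (adjusted p = 0.0017) and Ikzf3 rose by 1.66 ± 0.23 (adjusted p = 0.0039), so 2 of 5 Ikaros genes fell and 1 rose (2 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.69). Ikzf4 (-0.01 ± 0.16), Ikzf5 (0.31 ± 0.12) and Il7r (0.12 ± 0.08) did not pass in the cells compared, and Il7r was at -0.41 over all cells (adjusted p = 0.0256). With B cell-like leukaemia clusters alone Ikzf4 was at -1.70 (adjusted p = 3e-07), Il7r at 0.85 (adjusted p = 4.1e-05) and Ikzf2 at -7.32 (adjusted p = 1.4e-14), and in clusters with the T lineage score highest Ikzf5 was at 0.31 (adjusted p = 0.0407).

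B-lineage and progenitor genes rose together in the passaged leukaemia. All 14 B-cell genes rose on both counts, Vpreb1 by 8.51 ± 0.15. Among the largest rises were Vpreb3 (11.63 ± 0.34), Igll1 (11.62 ± 0.17) and Vpreb2 (10.94 ± 0.20), beside Nov (at least 4245-fold), the glycine decarboxylase gene Gldc (26798-fold by ratio of counts, 4809 to 1058510), the precursor B-cell aminopeptidase gene Enpep (12984-fold, 2330 to 512900), Cplx2 (12.28 ± 0.30) and Crhbp (11.77 ± 0.41). Without DN control 1 or 2 Cplx2 was at 13.48 and 11.60, Crhbp at 13.93 and 10.91, and the bound of Nov at 2149- and 2096-fold. Early progenitor genes rose in 13 of 18 cases and fell in 2 on both counts. Bcl11a rose by 4.85 ± 0.10 and Lyl1 by 5.76 ± 0.13, while Kit (-1.24 ± 0.21) and Hoxa9 (-1.15 ± 0.41) fell, but were at 0.42 and 1.40 over all cells. The Hoxa9 call also ended without DN control 2 (-0.73, adjusted p = 0.302), without leukaemia 1 or 2 (0.113 and 0.121), in DESeq2 (0.183) and with all 10 samples in a single fit (0.0613). Unfolded protein response genes rose in 15 of 17 cases on both counts, among them Herpud1 (1.50 ± 0.09) and Xbp1 (1.15 ± 0.08), and p53 targets in 14 of 16, among them Perp (6.09 ± 0.28) and Zmat3 (2.70 ± 0.12), but with B cell-like leukaemia clusters alone Perp was at 0.59 (adjusted p = 0.355). Neutrophil genes rose in 9 of 11 cases (10 adjusted over the list alone), Mpo to 7.01 ± 1.7 from 0.714 ± 0.0589 CPM and Ly6g to 7.33 ± 0.704 from 0.375 ± 0.244 CPM. The leukaemia cells compared include 172 and 117 neutrophil-like cells, a class left out of the DN cells, and with B cell-like leukaemia clusters alone Mpo was at 1.85 and Ly6g at 1.55 on the log2 scale, and Kit at -3.46 and Hoxa9 at -3.26. Over all cells the calls of Mpo (1.10, adjusted p = 0.252) and Ly6g (0.46, adjusted p = 0.613) ended, and that of Ly6g also with doublet calls kept (0.0868). Ly6g rose by 5.16 without DN control 1. By camera the adjusted p was 7.4e-08 (B cell), 2.5e-04 (progenitor), 1.3e-04 (unfolded protein), 4.1e-04 (p53) and 5.6e-04 (neutrophil). With an estimated correlation each of these had adjusted p = 0.526, and the neutrophil call was lost over all cells (adjusted p = 0.17).

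T-cell genes fell in the passaged leukaemia. Of 20 T-cell receptor genes 17 fell and none rose (18 down adjusted over the list alone), with Cd247 (-7.09 ± 0.14) and the kinase gene Lck (-6.03 ± 0.12) among them. The largest falls were Sh2d1a (10998-fold lower by ratio of counts, 3763 to 53331), Cd3g (-13.04 ± 1.04), Cd3d (-10.45 ± 0.31), the co-stimulatory receptor Cd28 (-10.20 ± 0.19), the T-cell commitment factor Bcl11b (-10.09 ± 0.98), the thymic homing receptor Ccr9 (-9.89 ± 0.20), Tcf7 (-9.42 ± 0.34) and Trat1 (-8.95 ± 0.79). Without DN control 1 or 2 the calls of Cd3g (adjusted p = 0.0595 and 0.0526), Bcl11b (0.0919 and 0.0845) and Trat1 (0.0808 and 0.0725) ended. Without leukaemia 1 Bcl11b fell by 12.09 and Trat1 by 12.79, without leukaemia 2 Cd3g fell by 11.94, Bcl11b by 9.21, Trat1 by 7.90 and Cd28 by 10.87, and Cd3g was at 0 in leukaemia 2. Over all cells Sh2d1a stood at -7.48, Cd28 at -6.90, Ccr9 at -6.84, Dtx1 at -4.55, Vpreb3 at 8.85, Igll1 at 9.56, Cplx2 at 9.33 and Lyl1 at 3.97. Of 19 T-lineage transcription factors 16 fell and 2 rose on both counts, with Tox (-5.76 ± 0.13) and Gata3 (-8.38 ± 0.21) down and Zbtb7b (2.53 ± 0.23, but 0.68 with B cell-like leukaemia clusters alone) and Tcf3 (0.78 ± 0.09) up. Notch genes fell in 11 of 15 cases and rose in 1 on both counts, with Notch3 (-5.72 ± 0.13) and Dtx1 (-8.67 ± 0.29) down and Hes5 (0.61 ± 0.19) up. The Hes5 call ended over all cells (0.04, adjusted p = 0.855), without DN control 1 (0.44, 0.167) and without leukaemia 1 (0.45, 0.102), and Dtx1 fell by 9.55 without leukaemia 1 and by 8.05 without leukaemia 2. S-phase genes fell in 30 of 39 cases (31 adjusted over the list alone), Cdca7 by 1.65 and Dtl by 1.07. Camera adjusted p was 1.2e-06, 8.2e-05, 0.004 and 9.2e-05 for these lists in order, and with an estimated correlation the adjusted p was 0.526, or 0.641 for S phase. IL7R-JAK-STAT5 genes went both ways, 10 up and 7 down of 19 on both counts, with Socs2 (6.40 ± 0.12) and Pim1 (3.26 ± 0.11) up and Stat5a (-2.03 ± 0.09) and Bcl2 (-2.07 ± 0.10) down, and the list was not called (camera adjusted p = 0.29).

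A comparison chosen after the data were seen set B cell-like leukaemia cells (3962 and 4240) against B cell-like cells of the passaged DN controls (128 and 135). The B cell-like cells of the groups differ in stage, with surrogate light chain genes in the leukaemia and mature B-cell genes and T-cell transcripts in the DN cells. The leukaemia cells were the more proliferative, with Mki67 at 581 ± 37.1 against 43.7 ± 11.9 CPM (SD, n = 2 each), and they held less of the mature B-cell genes Fcer2a (CD23; -11.23 ± 0.26), Iglc2 (-11.37 ± 0.24) and Igha (-10.11 ± 0.54). In edgeR 2460 genes rose and 2001 fell of 12391 tested, and without leukaemia 1 or 2 the total was 2725 of 7526 or 2490 of 7529. Ikzf2 was low in both, at 0.888 ± 0.096 against 4.77 ± 2.76 normalised CPM, from 81 counts against 6, with a log2 fold change of -2.37 ± 0.79 (adjusted p = 0.028). That call was lost without DN control 2 (-1.64, adjusted p = 0.348) and with no filter on low counts (-2.31, adjusted p = 0.0522), and Ikzf2 was below the filter without leukaemia 1 or 2. Ikzf3 fell by 1.21 (adjusted p = 1e-04), making 2 of 5 Ikaros genes down on both counts (camera adjusted p = 0.4), while Ikzf1 was at -0.32 ± 0.15, Ikzf5 at 0.31 ± 0.26 and Ikzf4, with 193 counts against 2, was 1.38-fold higher by ratio of counts (0.377 to 11.5). Mouse Il7r rose by 1.97 ± 0.20 (adjusted p = 7.7e-07).

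Cycle and respiration genes rose in the B cell-like leukaemia cells and interferon genes fell. G2 and M genes rose in 50 of 51 cases on both counts, Top2a by 3.48 ± 0.16 and Mki67 by 3.75 ± 0.19. S-phase genes rose in 36 of 39 cases (37 adjusted over the list alone), Rrm2 by 3.28 ± 0.26 and Mcm7 by 1.84 ± 0.16. Oxidative phosphorylation genes rose in 62 of 83 with 1 down (64 and 1 adjusted over the list alone), Cox5a by 1.60 ± 0.15 and Ndufa12 by 1.50 ± 0.15, with Cox7a2l down by 0.35. The Cox7a2l call ended without DN control 2 (-0.21, adjusted p = 0.281), leukaemia 1 (0.0609) or leukaemia 2 (0.158) and with no filter on low counts (0.145), and Rrm2 rose by 4.06 without DN control 1. Interferon genes fell in 19 of 24 cases and rose in 1 (20 and 2 adjusted over the list alone), with Irf7 (-4.19 ± 0.23) and Ifit3 (-4.37 ± 0.25) down and Gbp2 (1.63 ± 0.27) up. MHC class I genes fell in 8 of 15 (8 down and 1 up adjusted over the list alone), H2-Q7 to 66.8 ± 0.477 from 409 ± 3.17 CPM and H2-Q6 to 21.9 ± 2.24 from 134 ± 3.97 CPM. Immediate-early and stress genes fell in 16 of 20 cases and rose in 2 on both counts, with Fosb (-5.20 ± 0.16) and Hspa1b (-8.12 ± 0.32) down and Hsp90aa1 (0.94 ± 0.14) and Hspa8 (0.46 ± 0.15) up. The Hspa8 call ended without leukaemia 1 or 2 (0.47 and 0.17, adjusted p = 0.154 and 0.673). These calls had a camera adjusted p of 1.9e-11, 3.2e-08, 7.4e-08, 5.4e-06, 5e-04 and 2.7e-06 for these lists in order, and with an estimated correlation the adjusted p was 0.427, or 0.657 for oxidative phosphorylation. The largest rises were Gldc (at least 87.6-fold), the placental growth factor Pgf (at least 36.1-fold), Nov (at least 34.9-fold), Clgn (at least 24.2-fold), Vpreb2 (7.05 ± 0.37), Crhbp (117-fold by ratio of counts, 40.1 to 568), Tifab (7381 counts against 1, a ratio between 18.9 and 4166) and Myh10 (102-fold, 18.3 to 4024). Without DN control 1 or 2 the bounds were 40- and 47.6-fold for Gldc, 16.5- and 19.6-fold for Pgf, 15.9- and 19-fold for Nov and 11- and 13.2-fold for Clgn, and the control counts of Vpreb2, Crhbp, Tifab and Myh10 all lay in DN control 1. T-cell transcripts, markers of another cell type, were also lower, with 10 of 17 T-cell receptor genes down and none up (14 down and 2 up adjusted over the list alone; camera adjusted p = 1.1e-04, and adjusted p = 0.427 with an estimated correlation). Cd3g had 1 count against 235, 16448-fold lower by ratio of counts (2924 to 652411), and Bcl11b a log2 fold change of -10.50 ± 1.89, beside Il9r (-9.92 ± 0.47), Rgs1 (-9.79 ± 0.24) and Pxdc1 (-9.24 ± 0.50). The calls of Cd3g (adjusted p = 0.273 and 0.286) and Bcl11b (0.346 and 0.345) ended without leukaemia 1 or 2. Their levels in DN controls 1 and 2 were 73.3 and 307 CPM (Cd3g) and 19.7 and 160 CPM (Bcl11b). Without leukaemia 1 Il9r fell by 9.27, Pxdc1 by 8.52 and Iglc2 by 12.11, and without leukaemia 2 Il9r fell by 11.52, Pxdc1 by 11.33 and Igha by 10.98.

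The last comparison tested whether the passaged leukaemia differs from its DN controls in the same way as the progenitor IL7Rmut+TLX3 cells from theirs. The effects differed most in lineage genes, with the B-cell factor Pax5 higher by 12.35 ± 1.13 on the log2 scale in the passaged effect and Cd3g lower by 12.28 ± 0.89. Ikzf2 differed by -2.76 ± 0.50 (edgeR adjusted p = 0.0053) and Ikzf1 by -0.50 ± 0.12 (adjusted p = 0.0097; not over all cells, adjusted p = 0.143, nor with B cell-like leukaemia clusters alone, 0.0584, in non-cycling cells, 0.0868, or without progenitor DN control 1, 0.0576), making 2 of 5 Ikaros genes on both counts (camera adjusted p = 0.29). Ikzf3 (-0.37 ± 0.33), Ikzf4 (-0.33 ± 0.32), Ikzf5 (0.39 ± 0.19) and Il7r (-0.15 ± 0.53) did not pass, while Ikzf3 was at 0.92 in non-cycling cells and Ikzf4 at -1.99 with B cell-like leukaemia clusters alone (adjusted p = 5.2e-04). Of 14626 genes tested, the passaged effect was higher for 2792 and lower for 2965, and the total was 3835 without progenitor DN control 2. Over all cells it was higher for 1219 and lower for 2420, a total of 3639. Passage number and the preparation of the sets differ together, Xist and Ddx3y differ between leukaemia and DN controls in the passaged set alone, and only a set effect equal in thymocytes and leukaemia cancels.

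All 20 T-cell receptor genes were lower in the passaged effect, among them the kinase gene Zap70 (-6.84 ± 0.28). Cytotoxic genes were lower in 14 of 15 cases, among them Tbx21 (-10.05 ± 0.50) and Il2rb (-9.40 ± 0.47). All 14 B-cell genes were higher, Blnk by 9.63 ± 0.49 and Vpreb1 by 9.10 ± 0.43, and the counts adjusted over each of these lists alone were equal. S-phase genes were higher in 33 of 39 cases (34 adjusted over the list alone), Dtl by 1.201 ± 0.106 and Uhrf1 by 1.50 ± 0.14, and G2 and M genes in 38 of 51 (41), Ctcf by 0.63 ± 0.08 and Ttk by 1.08 ± 0.15. By camera the adjusted p was 1.1e-11, 1.9e-08, 6e-08, 6.6e-08 and 2.5e-07 in this order, and with an estimated correlation the adjusted p was 0.442, 0.272, 0.442, 0.518 and 0.534. The S-phase call ended in non-cycling cells (adjusted p = 0.077), as did that of Ttk (0.75 on the log2 scale, 0.532). IL7R-JAK-STAT5 genes were higher in 4 and lower in 10 of 19 cases (5 and 10 adjusted over the list alone), with Socs2 (2.18 ± 0.19) and Ccnd3 (1.03 ± 0.12) higher and Bcl2 (-4.33 ± 0.20) and Pim2 (-2.39 ± 0.13) lower. That call (adjusted p = 0.025) was lost with an estimated correlation (adjusted p = 0.442), over all cells (0.18), in clusters with the introduced IL7R (0.25), in non-cycling cells (0.17) and with B cell-like leukaemia cells alone (0.055). The other genes that differed most were Crhbp (12.32 ± 1.88), Cd79a (11.76 ± 0.82), Fcrla (11.72 ± 1.16), Vpreb2 (11.27 ± 0.86) and Mzb1 (11.21 ± 0.48) upwards, and Sh2d1a (-11.17 ± 0.69), Cd3d (-10.66 ± 0.42), Cd28 (-10.29 ± 0.44), Ccr9 (-8.35 ± 1.28), the granzyme gene Gzma (-8.28 ± 1.61), Trbc2 (-8.22 ± 1.08) and Trat1 (-7.83 ± 0.91) downwards. Several of these values rested on single samples. Without IL7Rmut+TLX3 sample 1 Cd79a was at 11.09 and Ccr9 at -9.09, and without sample 2 Cd79a was at 14.18, Ccr9 at -6.50, Blnk at 10.38 and Vpreb1 at 10.15. Without leukaemia 1 Gzma was at -10.83, Trbc2 at -10.08, Trat1 at -11.53 and Il2rb at -10.25, and without leukaemia 2 Gzma was at -7.44, Trbc2 at -7.44, Trat1 at -6.81 and Tbx21 at -9.03. Cecr2 and Ms4a1 (CD20), which also passed upwards, were at 0 in both IL7Rmut+TLX3 samples. Pax5, Vpreb2 and Mzb1 were at 0 in IL7Rmut+TLX3 sample 1, Crhbp and Fcrla in sample 2, and Cd3g and Tbx21 in leukaemia 2. Over all cells the differences were smaller for Sh2d1a (-4.20), Cd28 (-5.76), Ccr9 (-4.29), Gzma (-3.69), Cd3g (-10.64), Cd3d (-8.77), Trbc2 (-7.06), Trat1 (-6.68), Zap70 (-4.97), Tbx21 (-4.07), Il2rb (-4.33), Bcl2 (-3.02), Pim2 (-1.60), Ccnd3 (0.40), Blnk (7.28), Fcrla (7.14) and Mzb1 (9.25). With hashtags called by margin the calls of Crhbp (adjusted p = 0.0712) and Fcrla (0.0595) ended.

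Calls were shared between the progenitor and passaged comparisons, which share no library but both contrast spleen with thymus. Of 12513 genes tested in both, 2201 rose in both, against 1107 for independent lists, and 2247 fell in both, against 1312. Opposite calls were fewer than for independent lists, 530 up then down against 1323 and 336 down then up against 1098. Genes are not independent replicates, so these counts describe the lists.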

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

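The tests of the first pattern on mixing and depth were set before their values were seen, and the value within T-lineage cells was chosen only after the result was seen. Ikzf2 was lower over all cells of the IL7Rmut+TLX3 samples than over all cells of their DN controls. Mixing of classes alone gave 77 CPM against a measured 38.8 CPM in sample 1 and 63.3 against 80.5 CPM in sample 2, so a smaller T-lineage fraction can account for at least 0.507 of the log2 fall from 155 CPM. Lower Ikzf2 within T-lineage cells was left open by a log2 fold change of 0.10. Depth per cell did not account for it, since at 2000 UMIs per cell the lowest DN share of all cells with an Ikzf2 UMI was 1.90 times the highest IL7Rmut+TLX3 share.

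All tests of the second pattern were chosen only after the result was seen. Ikzf2 was lower in passaged leukaemia cells with the introduced IL7R than in DN T-lineage cells, and most of those cells were B cell-like. B cell-like cells without the introduced IL7R held at most 15.1 CPM of Ikzf2 in any sample. B-cell identity can thus account for a low level, though B cell-like leukaemia cells held less (0.82 and 0.956 normalised CPM). A loss of Ikzf2 in every cell that carries the introduced IL7R was not borne out, since the highest class reached 192 CPM in the lower leukaemia. Whether Ikzf2 is low beyond B-cell identity was left open. The log2 fold change of -2.37 did not pass in every alternative, and the DN cells held T-cell transcripts.

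All tests of the third pattern were chosen only after the result was seen. Neutrophil-like clusters with the introduced IL7R in the IL7Rmut+TLX3 samples held Cd3e and Cd3d. Free RNA of T cells does not account for it, with Cd3e at 16.9 times or more its level in neutrophil-like clusters of the same library without the introduced IL7R. Doublets of a T cell and a neutrophil do not either, with the ratio of Lck to Cd3e at most 0.199 times that of T lineage-like clusters. Descent of both from a single progenitor was left open, with the share of cells holding an introduced IL7R UMI at least 1.67 times that of T lineage-like clusters.

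The passaged and progenitor effects differed by a test of the difference itself for Ikzf2 (-2.76 on the log2 scale), for Ikzf1 (-0.50) and for 5757 genes in all. Introduced human IL7R, which no gene comparison used as an outcome, was above its level of 0 in the DN controls in 40.1% and 47.5% of IL7Rmut cells, 38.7% and 32.1% of IL7Rmut+TLX3 cells and 50.3% and 51.1% of passaged leukaemia cells. Introduced human TLX3 was above its level of 0 in the DN controls in 0.493% and 0.482% of IL7Rmut+TLX3 cells and in 1.07% and 0.998% of passaged leukaemia cells.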

How the results depend on the processing

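Most alternatives were chosen before the data were examined. Those on clusters with the introduced IL7R, on B cell-like cells, on clusters with the T lineage score highest and on leaving out the top doublet scores were chosen after the data were seen, as was the use of clusters with the introduced IL7R for the passaged leukaemia. Ikzf2 kept its direction and its side of the threshold in 92 of 110 alternatives, including all 17 for the passaged leukaemia (log2 fold -7.32 to -2.59, adjusted p = 8.6e-139 to 7.6e-04) and all 24 for the difference between sets (-7.35 to -1.90, adjusted p = 4.9e-10 to 0.0285). With 1 sample left out, the adjusted p leaves out the spread of its group. Leaving out 1 sample at a time gave -2.79 to -2.59 and -3.24 to -1.97. Of 4872 values of other named genes 4539 kept both, of 392 single gene lists 310, of 112 gene counts 95, of 224 counts by direction 189, of 38 counts of lists 30, of 28 antibody gates 5 and of 20 Ikzf2 shares 2 stayed within 1.5 times. Shares were not tested.

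For IL7Rmut+TLX3 against DN, Ikzf2 was -1.19 over all cells (adjusted p = 0.0296), and the highest adjusted p over the alternatives was 0.981. With 1 sample left out Ikzf2 was -0.65 (without IL7Rmut+TLX3 sample 2) to 0.58 (without sample 1). For IL7Rmut against DN it was 1.14 with no filter on low counts (adjusted p = 0.149), 0.69 over all cells (0.141), 0.33 in cells with no UMI of Mki67 or Top2a (0.5) and 1.202 in clusters with the introduced IL7R (0.0781). With 1 sample left out it was 1.17 to 1.2045, at 1.19 and 1.17 without DN 1 and 2 (adjusted p = 0.166 and 0.175) and 1.196 and 1.2045 without IL7Rmut 1 and 2 (0.126 and 0.127), over a range of 1.3e-07 to 0.5. For IL7Rmut+TLX3 against IL7Rmut it was -1.88 over all cells (adjusted p = 0.0371) and -1.69 in clusters with the introduced IL7R (0.0474). With 1 sample left out it was -1.85 (without IL7Rmut+TLX3 2) to -0.61 (without 1). In B cell-like cells it was -2.37 with the replicate block (adjusted p = 0.08), -2.31 with no filter on low counts (0.0522) and -2.88 and -1.64 without DN 1 and 2 (0.0139 and 0.348), over a range of 0.0033 to 0.348. Without leukaemia 1 or 2 it was below the filter on low counts and has no value. The cause was not tested.

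Reversed genes were Ifi44 in IL7Rmut+TLX3 against DN over all cells (0.29, adjusted p = 0.807), Il7r (-0.41, adjusted p = 0.0256), Kit (0.42, 0.0621) and Hoxa9 (1.40, 0.0569) in the passaged leukaemia over all cells, and Ikzf3 in the difference between sets in cells with no UMI of Mki67 or Top2a (0.92, 0.0075). The cause was not tested.

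Gene counts with 1 sample left out, which leaves fewer samples, were 5116 to 8486 for IL7Rmut+TLX3 against DN (5296 and 5116 without DN 1 and 2), 4042 to 9043 for IL7Rmut against DN (4042 and 4064 without DN 1 and 2), 7480 to 8900 for the passaged leukaemia, 3835 (without progenitor DN 2) to 6012 for the difference between sets and 2490 to 3925 in B cell-like cells (2725 and 2490 without leukaemia 1 and 2). For IL7Rmut+TLX3 against IL7Rmut, 1778 genes became 1118 with the replicate block, 258 in cells with no UMI of Mki67 or Top2a, 3984 in clusters with the introduced IL7R, 10 with only those groups and 4 to 4662 with 1 sample left out (15 and 15 without DN 1 and 2, 6 and 4 without IL7Rmut 1 and 2, 4662 without IL7Rmut+TLX3 2). Over all cells the difference between sets held 3639 genes, 1219 higher and 2420 lower against 2792 and 2965. Lists called with an estimated correlation numbered 0 in each comparison, and fry called 5 for IL7Rmut+TLX3 against IL7Rmut and 25 in B cell-like cells. Overlap at 2-fold or more was 3.47 (up) and 3.62 (down) times expected. At 0.5 and 2 times the threshold, CD8a-positive shares were 5.91% and 0.25% in DN and 96.9% and 72.9% in IL7Rmut, and B220-positive shares 37.3% and 0.937% in passaged DN and 99.6% and 73.3% in leukaemia. The cause was not tested.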

Other observations

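B cell-like cells of passaged leukaemia 1 and 2 transcribed immunoglobulin constant regions, with fewer Ighv segments per Ighm than B cell-like cells of the passaged DN controls and no such difference for Igkv. Ighm stood at 1612 and 1488 raw CPM, Igkc at 2492 and 2184 CPM and the recombinase gene Rag1 at 112 and 94.5 CPM. Ighv segments gave 0.0975 and 0.0788 UMIs per 100 Ighm UMIs, against 2.34 and 2.05 in B cell-like cells of the passaged DN controls and 0.169 and 0.175, from 2 Ighv UMIs each, in those of the progenitor DN controls. Igkv segments gave 1.75 and 1.25 UMIs per 100 Igkc UMIs in the leukaemias, 1.35 and 1.62 in the passaged DN controls and 0.381 and 0.521 in the progenitor DN controls.

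A cluster of 408 cells in the IL7Rmut+TLX3 library led by Foxp3, Ctla4, Icos and Tnfrsf4, genes of regulatory T cells, held 492 raw CPM of Ikzf2. Sex-linked transcripts set the passaged leukaemias apart from all other samples. Xist, which female cells express, had a UMI in 98% and 97.4% of progenitor DN cells, 87.6% and 91.8% of IL7Rmut cells and 69.5% and 81.8% of IL7Rmut+TLX3 cells, against 0.186% and 0.139% of passaged leukaemia cells.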
